A study of Mus musculus with 11 samples.

How the data were processed

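Expression was measured in 6 liver and 5 spleen samples on Illumina mouse bead arrays with 45281 probes. Total RNA from frozen tissue was amplified, labelled with biotin and hybridised, per the labels' protocols. The deposited intensities are bead-summarised probe signals made with GenomeStudio 1.6.0, per the submitters' processing notes, and their values show no background subtraction and no scaling between arrays. The deposited detection p-values stand beside each signal, per the file headers, and how they were computed is not given in the sources used here. The deposited series matrix holds log2 values, and the step that made them is not given in the sources used here. They were tested against the signals and equal the log2 of the signals after quantile normalization over all 11 arrays without background subtraction, with a largest gap of 0.00172. Each matrix column had a rank correlation of 1 with its own signals and of at most 0.854 with those of another array, and its median lay between 5.10 and 5.11.

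All values were computed from the unscaled signals with limma 3.58.1 in R 4.3.3. The arrays of each tissue were processed with neqc, that is, normexp background correction with the background inferred from the detection p-values, an offset of 16, quantile normalization and log2. Probes were kept with a detection p-value under 0.05 on at least 2 arrays of the tissue, and a gene with several kept probes was represented by the one with the highest mean. Probe names came from the platform annotation, which gives 1 gene symbol for 34885 probes, several for 18 and none for 10378. Entrez identifiers of 34807 probes matched the mouse gene table, which changed 0 symbols. Unnamed probes were tested under their own identifiers. This left 12800 features in liver (10246 named) and 14179 in spleen (11025 named), and 16179 (12452 named) where both tissues were processed together.

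Each tissue was fitted with 1 mean per group by lmFit and tested with the moderated statistic of eBayes and Benjamini-Hochberg adjustment at 0.05. The residual degrees of freedom were 3 in liver and 2 in spleen, to which the moderation added 5.11 and 4.74. Each dose was compared with control and with the other dose, and the mean of both doses with control. The difference in response between tissues was tested in 1 fit of all 11 arrays, with 5 residual degrees of freedom. Where the dimmer group was undetected on all of its arrays, the fold change is given as a lower bound, with each of its arrays set to at least the lowest value of any probe detected on that array.

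The design, the comparisons, the rule for naming genes, the gene lists and most alternatives were fixed before the data were examined. The rule names up to 12 genes per direction with an adjusted p under 0.05 and no overlap between groups. Where fewer than 5 pass, it names the 5 with the smallest raw p, with Y chromosome genes and Xist left out, as values and not as changes. It adds up to 4 members of each list by raw p, of which the text gives the first 1 to 4, and Ssrp1, Supt16, Trp53, Cdkn1a, Nfkbia and Hspa1b in every comparison where they were tested. The unnamed probes called were added after their values were seen. Cd79b and Cd22 were used as spleen markers in the tissue check, and this choice was made after the data were seen. The 40 lists hold 698 genes, of which 637 are named by a probe, and they cover targets of drug-responsive factors, liver metabolism, stress, growth, sex bias and markers of cell types. Lists with at least 3 kept genes, 38 in liver and 36 in spleen, were tested with camera at a preset correlation between genes of 0.01 and again with the correlation estimated from the data. Counts of list members are also given adjusted over the list alone. The list tests between the doses were added after the data had been seen.

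The alternatives were scaling to the 75th percentile in place of quantile normalization, no background correction (signals under 1 set to 1), and the authors' normalized values. Others were an offset of 50, no detection filter, a strict filter (detection p-value under 0.01 on every array), every probe tested, all arrays fitted together, and moderation with an intensity trend and robust hyperparameters. The spleen arrays at 0.2 mg/ml share the number 62 in their labels, so they were also averaged and counted as 1 sample. Each array was left out in turn where the comparison could still be formed, which for spleen against control excludes the lone control. A group left with 1 array was assumed to vary like the other groups. The lists were rerun only with the estimated correlation, the authors' normalized values, no background correction and each array left out. The dose correlation was set against 100 simulations of unchanged groups with the same shared controls, and those for left-out arrays and 75th percentile scaling were added after the data were seen.

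The steps were tested on simulated data with 200 changed genes, made for the comparison at 0.2 mg/ml with control in each tissue. With each gene's moderated spread, 88.1% of genes changed by 1 on the log2 scale were recovered in liver and 4.48% in spleen, and 100% and 89.6% of those changed by 2. The share of false calls was then 11.5% of 217 in liver and 12.8% of 148 in spleen, above the nominal level. With spreads drawn from the fitted prior, a simulation added after the first, the recovered shares were 49.3% and 1.49% for a change of 1, and 94.0% and 38.8% for a change of 2. For a change of 3 they were 98.5% and 97.0%, and the false shares were 4.17% and 1.09%. A list shifted by 0.5 was called with the preset correlation in liver (adjusted p = 6.9e-25) and spleen (adjusted p = 8.6e-07). With the estimated correlation it was called in liver (adjusted p = 0.0450) and missed in spleen (adjusted p = 0.850). Genes were drawn independently, in 1 data set per tissue, so this does not test lists whose genes vary together.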

Results

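Total RNA from mouse liver and spleen was hybridised to Illumina bead arrays, 1 array per sample, to measure the expression of 45281 probes. The mice carried a Her2/neu transgene, which drives mammary tumours, and drank plain water or water with Curaxin-137 for 10 weeks, from 4 to 14 weeks of age. Curaxin-137 is a small molecule of the curaxin class, which bind DNA, trap the histone chaperone FACT on chromatin, activate p53 and inhibit NF-kB. The liver had 2 control arrays (replicates 1 and 25), 2 arrays at 0.1 mg/ml (replicates 43 and 55) and 2 at 0.2 mg/ml (replicates 73 and 85). The spleen had 1 control array (replicate 8), 2 arrays at 0.1 mg/ml (replicates 56 and 32) and 2 at 0.2 mg/ml (replicates 62 and 62_86). The mean signal per array ran from 94.7 on spleen replicate 32 to 219 on spleen replicate 56, both at 0.1 mg/ml. Of the probes, 35.8% to 43.2% were detected. The number of arrays limits the precision of every value below, and the p-values measure the spread between these samples only. The spleen control has no replicate, so every spleen comparison with control assumes that it varies as the treated spleens do.

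The genes that mark each organ were found where its label puts them. Apoa1, which encodes the main protein of high-density lipoprotein, had a mean log2 intensity of 13.3 on the 6 liver arrays and 4.64 on the 5 spleen arrays. Cd79b, a part of the B cell receptor, read 11.9 in spleen and 4.36 in liver, and Cd22, a B cell surface lectin, read 9.46 and 4.16. The probe for albumin, Alb, gave little signal even in liver, at 5.50, against 4.21 in spleen.

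The first comparison asks what the lower dose did to the liver. Sterol synthesis genes read lower as a group at 0.1 mg/ml than in control liver, and heat shock genes, which encode chaperones for damaged proteins, read higher. With a correlation between genes estimated from the data, these and all other list calls of the comparison were lost (adjusted p = 0.703). The sterol call also ended without control replicate 25, and the heat shock call without control replicate 1 or replicate 55. Neutrophil markers, acute phase genes, interferon response genes and cell cycle genes read lower too, but these 4 groups took their direction from control replicate 25. No single gene passed its test.

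In the sterol synthesis list, 17 of 18 genes read lower, with a median log2 change of -0.49 (camera, adjusted p = 2.5e-06; adjusted p = 0.703 with an estimated correlation, for this and each other list of the comparison). Its lowest raw p-values belonged to Sc5d, a late enzyme of cholesterol synthesis, at -0.79, and Srebf2, the transcription factor that drives the pathway, at -0.50. Heat shock genes had a median of 0.31, with 18 of 21 higher (adjusted p = 2.8e-04), led by the chaperone genes Hspa1a at 1.97 and Hspb1 at 0.66. Fibroblast markers read higher in 10 of 11 genes (median 0.31, adjusted p = 0.00115), among them the collagen gene Col6a1 at 0.57 and the matrix proteoglycan gene Lum at 0.66. Male-biased liver genes read higher in 8 of 9 (median 0.40, adjusted p = 0.00138), with the fatty acid hydroxylase gene Cyp4a12a at 0.70 and the carboxylesterase gene Ces3b at 0.45. Endothelial markers read higher in 11 of 12 (median 0.24, adjusted p = 0.00621), led by the sinusoidal lectin gene Clec4g at 0.39 and Oit3 at 0.36. Neutrophil markers read lower in 7 of 7 (median -1.84, adjusted p = 7.9e-04), with the calprotectin genes S100a9 at -2.44 and S100a8 at -2.74. Acute phase genes read lower in 23 of 24 (median -0.27, adjusted p = 0.00115), among them the interleukin-1 receptor antagonist gene Il1rn, at least 1.31-fold lower, and Itih4, at -0.45. Interferon response genes read lower in 24 of 32 (median -0.13, adjusted p = 0.00665), with the ubiquitin-like modifier gene Isg15 at -0.66 and the tetherin gene Bst2 at -0.46. Cell cycle genes read lower in 21 of 25 (median -0.28, adjusted p = 0.0126), with the mitotic checkpoint gene Bub1b at least 1.12-fold lower and the replication clamp gene Pcna at -0.52. Of the members of these 9 lists, 0 passed when adjusted over the list alone and 0 over all genes tested.

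Control replicate 25 decided much of this: without it 1 of the 9 list calls was kept, and the medians turned to 0.19 for acute phase genes, 0.03 for interferon response genes and 0.03 for neutrophil markers. Cell cycle genes turned to 0.20 and were called in the other direction (adjusted p = 9.6e-04). The sterol median without it was -0.15, the male-biased median 0.13, the fibroblast median 0.12 and the endothelial median 0.10, and these calls ended too. The heat shock call ended without control replicate 1 (median 0.15) or replicate 55 (0.16), the interferon call without replicate 55 (-0.16) and the cell cycle call without replicate 43 (-0.20).

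By limma, 0 of 12800 features had an adjusted p under 0.05 at 0.1 mg/ml, the smallest being 0.984. At an unadjusted p under 0.05 there were 513, 273 higher and 240 lower, where chance gives 640, and 784 with 75th percentile scaling. Calls appeared only when a control liver was left out, and the spread then came from the treated pairs alone. The control livers were the least alike pair of liver arrays (correlation 0.971, against 0.989 and 0.992 within the doses). Those calls therefore lend no weight to the genes named next. The higher genes with the smallest raw p were Mknk2, a kinase gene of translation control, at 0.99 (SE 0.16), the lipoprotein lipase inhibitor gene Angptl4 at 0.92 and Mbd1, which binds methylated DNA, at 0.93. Ppp1r3g, a glycogen-targeting phosphatase subunit, read 3.03 higher (SE 0.57), and the serine protease gene Prss53 read 1.17 higher. The lower genes were the galactosyltransferase gene B3galt1 at -0.87, the membrane-anchor attachment gene Pigt at -1.09, the zinc finger gene Zc3h6 at -0.76 and the phosphatase inhibitor gene Ppp1r1b at -0.88. Kcnj8, a potassium channel gene, was undetected in both treated livers and read at least 1.45-fold lower. Angptl4 was the only member of a list without a call to pass adjusted over its list alone, that of PPAR-alpha targets. Among the genes followed in every comparison, the FACT subunit gene Supt16 read -0.17 (its other probe went the opposite way), the p53 target Cdkn1a -0.18, the NF-kB target Nfkbia -0.12, and the chaperone gene Hspa1b at least 1.40-fold higher, with adjusted p from 0.984 to 0.998.

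At the higher dose, livers with 0.2 mg/ml were compared with the same control livers. Fatty acid synthesis and sterol synthesis genes read lower as groups, and markers of macrophages, fibroblasts and endothelium read higher, as did interferon response genes. With an estimated correlation these calls were lost (adjusted p = 0.723). The single genes nearest to a call were Csad, an enzyme of taurine synthesis, Atf5, a transcription factor of the stress response, and Cyp3a11, the main drug-metabolising cytochrome of mouse liver. All 3 read lower on both arrays at 0.2 mg/ml than on both control arrays.

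Fatty acid synthesis genes read lower in 14 of 16 (median -0.40, adjusted p = 3.5e-05; adjusted p = 0.723 with an estimated correlation, as for each called list here). Fasn, the fatty acid synthase gene, was at least 1.36-fold lower and the pyruvate kinase gene Pklr read -0.65, and these 2 passed adjusted over the list alone, against 0 over all genes. Macrophage markers read higher in 13 of 13 (median 0.38, adjusted p = 1.0e-04), with the phagocytic receptor gene Timd4 at 0.78 and the lysozyme gene Lyz2 at 0.98. Interferon response genes read higher in 25 of 32 (median 0.29, adjusted p = 2.5e-04), led by the guanylate-binding protein genes Gbp2 at 1.15 and Gbp3 at 0.78. Sterol synthesis genes read lower in 17 of 18 (median -0.34, adjusted p = 3.9e-04), with the mevalonate pathway gene Mvd at -1.16 and Sc5d at -0.89. In both of these lists and in the macrophage list 0 members passed adjusted over the list alone and 0 over all genes. Fibroblast markers read higher in 9 of 11 (median 0.29, adjusted p = 9.0e-04) and endothelial markers in 10 of 12 (median 0.33, adjusted p = 0.00127). Adjusted over the list alone, 2 genes passed in each, Lum at 0.94 and the matrix gene Reln at 0.82, and the sinusoidal genes Oit3 at 0.92 and Clec4g at 0.75, against 0 over all genes. Gluconeogenesis and fasting genes read higher in 8 of 11 (median 0.18, adjusted p = 0.0475), and the insulin signalling gene Irs2 at 1.08 and the transaminase gene Gpt2 at 0.64 passed adjusted over the list alone. Neutrophil markers read lower in 7 of 7 (median -1.21, adjusted p = 0.0469), with Retnlg at least 2.19-fold lower and S100a9 at -1.77.

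In 10 lists without a call, 13 members passed adjusted over their list alone, 10 higher and 3 lower, with 0 over all genes. Among them, in the CAR and PXR list (adjusted p = 0.520), Cyp3a11 read -1.41 and its relative Cyp2c50 read 0.83. The asparagine synthetase gene Asns read -1.64, the phosphatase gene Dusp1 2.16, the clock gene Per2 1.01 and the sterol exporter gene Abcg8 0.94. The cytokine genes Il1b at 1.11 and Ccl5 at 0.90 passed in the NF-kB target list, whose adjusted p was 0.0935.

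Without control replicate 25, 3 of the 8 list calls were kept, the neutrophil median turned to 0.14, and the medians were -0.04 for sterol synthesis, -0.20 for fatty acid synthesis, 0.31 for fibroblasts and 0.20 for endothelium. Without control replicate 1, the calls of interferon response (0.09), gluconeogenesis (0.08) and macrophage genes (0.12) ended. The gluconeogenesis and neutrophil calls ended also without replicate 43 (0.19 and -1.21), 55 (0.18 and -1.22) or 73 (0.09 and -0.92).

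By limma, 0 features had an adjusted p under 0.05 at 0.2 mg/ml, the smallest being 0.179, and 1124 had an unadjusted p under 0.05, 632 higher and 492 lower. Leaving out either control liver raised the count, but the spread then came from the more alike treated pairs alone, so those calls lend no weight to the genes named here. Csad read -2.54 (SE 0.29) and Atf5 -1.75 (SE 0.22), each with an adjusted p of 0.179, and Cyp3a11 read -1.41 (SE 0.19, adjusted p = 0.206). These 3 passed with an intensity trend and robust hyperparameters in the moderation (adjusted p = 0.0498 each), and Csad passed with 75th percentile scaling (adjusted p = 0.0307). The membrane protein genes Smagp and Sel1l3 read -1.12 and -1.26. The higher genes were the nuclear factor gene Tox at 1.52 (SE 0.19, adjusted p = 0.179), the ERK phosphatase gene Dusp6 at 1.32 and Gpcpd1, an enzyme of choline metabolism, at 1.20. Ddo, an oxidase of D-amino acids, read 1.10 and the cell cycle inhibitor gene Cdkn1c read 0.91. Supt16 read 0.34, Cdkn1a 0.61, Nfkbia -0.24 and Hspa1b at least 1.68-fold higher, with adjusted p from 0.566 to 0.837.

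**Figure D1:**
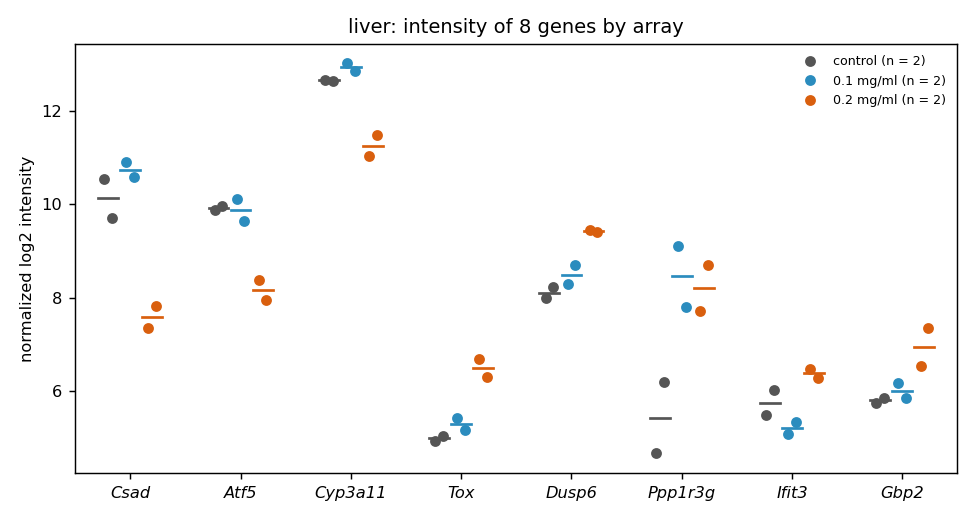
Log2 intensity (y axis) of 8 genes on the 6 liver arrays, by group (x axis), where points are arrays and lines are group means. Csad read 10.5 and 9.71 in the controls, 10.9 and 10.6 at 0.1 mg/ml, and 7.35 and 7.83 at 0.2 mg/ml.

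Set directly against each other in liver, the doses gave their smallest p-values for interferon response genes, which read higher at 0.2 than at 0.1 mg/ml, and for Csad, Cyp3a11 and Atf5, which read lower and did not pass, with list tests chosen after the data had been seen. Interferon response genes read higher in 26 of 32 (median 0.47, adjusted p = 1.4e-08; adjusted p = 0.729 with an estimated correlation, as for each called list here). Adjusted over the list alone, 12 of them passed, against 0 over all genes, led by Ifit3, which blocks translation of viral RNA, at 1.17, and the antiviral enzyme gene Rsad2 at 0.92. The antigen processing genes Psmb8 and Tap1 followed, at 0.80 and at least 1.51-fold higher. Macrophage markers read higher (11 of 13, median 0.41, adjusted p = 0.0112), as did NF-kB targets (13 of 17, median 0.20, adjusted p = 0.0247) and acute phase genes (22 of 24, median 0.32, adjusted p = 0.0288). Tnfaip2, at 0.73, was the 1 NF-kB target to pass adjusted over the list alone. Fatty acid synthesis genes read lower (13 of 16, median -0.31, adjusted p = 0.0112), as did NRF2 targets (10 of 14, median -0.32, adjusted p = 0.0231), male-biased liver genes (8 of 9, median -0.43, adjusted p = 0.0352) and unfolded protein response genes (12 of 17, median -0.12, adjusted p = 0.0374). The NRF2 targets Ephx1 at -0.79, Gclm at -0.57 and Srxn1 at -0.61, which detoxify epoxides, make glutathione and repair oxidised proteins, passed adjusted over the list alone, as did Asns at -1.54 in the last list. In 11 lists without a call, 19 members passed adjusted over their list alone, 13 higher and 6 lower. Among them, in the CAR and PXR list (adjusted p = 0.537), were Cyp2b9 at 2.93, Cyp2c54 at 1.56, Cyp2c50 at 1.01 and Cyp3a11 at -1.68. Without replicate 55, 2 of the 8 calls were kept, and the medians of the lost calls were 0.32 (acute phase), 0.35 (macrophages), -0.32 (male-biased), 0.14 (NF-kB), -0.28 (NRF2) and -0.15 (unfolded protein response). Without replicate 85, the macrophage (0.09), NF-kB (0.24) and unfolded protein response (-0.10) calls ended, and without replicate 73 the acute phase (0.29) and male-biased (-0.22) calls. The unfolded protein response call ended also without background correction (median -0.11, adjusted p = 0.0551).

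By limma, 0 features differed between the liver doses at an adjusted p under 0.05, and 1217 had an unadjusted p under 0.05, 656 higher and 561 lower at 0.2 mg/ml. Csad came nearest, at -3.15 (SE 0.29, adjusted p = 0.0571), lower on both arrays, followed by Cyp3a11 (adjusted p = 0.125) and Atf5 at -1.72 (adjusted p = 0.153). Csad passed with 75th percentile scaling, the strict detection filter, the authors' normalized values, all arrays fitted together or an intensity trend with robust hyperparameters, with adjusted p from 0.00785 to 0.0318, and Cyp3a11 passed in the last 3 of these. Leaving out either control liver raised the count, but again with the spread from the more alike treated pairs alone. The proteoglycan gene Cspg5 read -1.34 and 9130409I23Rik read -1.12. The higher genes were the desmosomal cadherin gene Dsg1c at 1.6, Tox at 1.21, the vesicle protein gene Syt1 at 1.09, Bhlhb9 at 0.97 and Decr1, an enzyme of fatty acid oxidation, at 0.93. Supt16 read 0.51, Cdkn1a 0.78, Nfkbia -0.12 and Hspa1b 0.26, with adjusted p from 0.450 to 0.902.

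Averaging both doses against control in liver gives their mean change, which a change at 1 dose alone can also produce. Sterol synthesis genes gave the clearest group value, and fibroblast, endothelial and macrophage markers read higher beside them. Sterol synthesis genes read lower in 17 of 18 (median -0.41, adjusted p = 1.1e-06; adjusted p = 0.780 with an estimated correlation, as for the other lists here unless given), with Sc5d at -0.84 and Mvd at -1.04. Fatty acid synthesis genes read lower in 15 of 16 (median -0.33, adjusted p = 1.4e-04), with Fasn at -0.42. Fibroblast markers read higher in 11 of 11 (median 0.34, adjusted p = 1.0e-04; adjusted p = 0.666 with an estimated correlation) and macrophage markers in 13 of 13 (median 0.20, adjusted p = 0.00109; adjusted p = 0.824 with an estimated correlation). Endothelial markers read higher in 10 of 12 (median 0.25, adjusted p = 3.4e-04), heat shock genes in 15 of 21 (median 0.19, adjusted p = 0.00337) and gluconeogenesis genes in 9 of 11 (median 0.29, adjusted p = 0.0322). Neutrophil markers read lower in 7 of 7 (median -1.53, adjusted p = 0.0010). Adjusted over the list alone, Lum at 0.80, Oit3 at 0.64 and Clec4g at 0.57 passed, and, in lists without a call, Dusp1 at 1.71, Abcg8 at 0.79 and Angptl4 at 0.75, against 0 over all genes. Without control replicate 25, 3 of 8 calls were kept and the medians were -0.08 (sterol), -0.07 (fatty acid), 0.20 (fibroblasts), 0.15 (endothelium) and 0.08 (neutrophils). Without control replicate 1, the heat shock (0.11), macrophage (0.02) and gluconeogenesis (-0.04) calls ended. The heat shock call ended also without replicate 55 (0.11) or 85 (0.12), the macrophage call without replicate 85 (0.14), and the gluconeogenesis call without replicate 43 (0.27) or 73 (0.15).

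By limma, 0 features passed for either dose in liver, with a smallest adjusted p of 0.707, and 759 had an unadjusted p under 0.05, 431 higher and 328 lower. Calls appeared only when a control liver was left out, with the spread then from the more alike treated pairs alone. Ppp1r3g read 2.90 (SE 0.50), Tox 0.91, Mknk2 0.76, the actin-binding gene Ablim3 0.75 and the splicing factor gene Mbnl2 0.78. Smagp read -0.83, the signal recognition receptor gene Srpr -0.79, the water channel gene Aqp8 -1.38 and Atf5 -0.89, and Kcnj8 was at least 1.45-fold lower. The Atf5 value came from the higher dose, with means of 9.91 in control, 9.88 at 0.1 mg/ml and 8.16 at 0.2 mg/ml. Tox had means of 4.98, 5.29 and 6.50 in these groups. Supt16 read 0.08 (-0.06 with 75th percentile scaling), Cdkn1a 0.21, Nfkbia -0.18 and Hspa1b at least 1.53-fold higher, with adjusted p from 0.846 to 0.976.

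In spleen, the lower dose was compared with the single control array. Cell cycle, erythroid and neutrophil genes read higher as groups at 0.1 mg/ml, most of it on the array of replicate 32, together with genes of oxidative phosphorylation, heat shock and endothelium. With an estimated correlation these calls were lost (adjusted p = 0.825). C1qc and Fcna, which encode parts of the complement system made by macrophages, were among the single genes with the smallest p. Prf1, the perforin gene of killer cells, and Zbtb2, a zinc finger repressor gene, read lower.

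Cell cycle genes read higher in 28 of 29 (median 1.19, adjusted p = 5.5e-10; adjusted p = 0.825 with an estimated correlation, as for each called list here), with the DNA helicase genes Mcm6 at 1.39 and Mcm7 at 1.10. Erythroid markers read higher in 11 of 11 (median 2.05, adjusted p = 4.5e-06), with the blood group gene Ermap at 2.43 and the erythroid transcription factor gene Klf1 at 2.66. Neutrophil markers read higher in 13 of 14 (median 1.91, adjusted p = 2.1e-06), with the granule protein genes Lcn2 at 2.59 and Ngp at 1.85. Without replicate 32 these medians were 0.50, 0.71 and 0.78, still called, with the spread then taken from replicates 62 and 62_86 alone. Genes of oxidative phosphorylation read higher in 18 of 23 (median 0.43, adjusted p = 0.00103), with the respiratory chain genes Cox6a1 at 1.13 and Ndufa9 at 1.00, a call that ended without replicate 32 (median 0.16). Endothelial markers read higher in 9 of 11 (median 0.44, adjusted p = 0.0174), with Clec4g at 1.41, and heat shock genes in 14 of 21 (median 0.49, adjusted p = 0.0174). Both calls ended without replicate 56 (medians 0.34 and 0.17). Adjusted over the list alone, the co-chaperone genes Dnajb1 at 1.18, Fkbp4 at 1.23 and Stip1 at 1.16 passed, against 0 over all genes. In 8 lists without a call, 13 members passed adjusted over their list alone, 8 higher and 5 lower. They were C1qc, C1qb at 1.49, C1qa at 1.11, Angptl4, Pdk4, the p53 target Phlda3 at 1.45, Selenbp2 at 0.97, the complement gene C6 at 0.83, Amy2a5, Prf1, Siglech, a receptor gene of plasmacytoid dendritic cells, at -1.84, the retinol storage gene Lrat, at least 2.48-fold lower, and the matrix gene Dcn at -1.10.

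By limma, 0 of 14179 features passed at 0.1 mg/ml in spleen, with a smallest adjusted p of 0.427, and 1388 had an unadjusted p under 0.05, 661 higher and 727 lower, where chance gives 709. With 75th percentile scaling 642 did, fewer than by chance. All arrays fitted together gave 48, with 9 of the 10 named here. Leaving out replicate 56 gave 1996 genes and leaving out replicate 32 gave 1232, but the spread then comes from replicates 62 and 62_86 alone, which may be 1 animal, so these counts may set differences between mice against technical noise. C1qc read 1.79 (SE 0.27), Angptl4 1.81, Fcna 1.64, the kinase gene Pdk4, which spares glucose in fasting, 1.6, and the angiotensin receptor gene Agtr1a 1.78. Zbtb2 read -1.85 (SE 0.28), the pancreatic amylase gene Amy2a5 -1.85, Prf1 -1.72, the class I histocompatibility gene H2-M2 -1.56 and Erich5 -1.63. Supt16 read -0.46, Cdkn1a 1.49 and Nfkbia 0.22, with adjusted p from 0.482 to 0.910, and Hspa1b was not detected often enough in spleen to be tested.

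At 0.2 mg/ml, interferon response genes gave the lowest list p-value of the comparisons with control, though the call was lost with an estimated correlation (adjusted p = 0.387). The complement genes C1qb and C1qc, the interferon-induced chemokine gene Cxcl10 and the protease inhibitor gene Serpina3f had the smallest raw p-values of the named genes that read higher. Interferon response genes read higher in 28 of 32 (median 0.72, adjusted p = 2.5e-15). Adjusted over the list alone 12 passed, against 0 over all genes, led by Ifit3 at 2.14, Gbp2 at 1.77, Ifi27l2a at 1.75 and Oasl2, a sensor-like gene, at 1.63. Macrophage markers read higher in 9 of 11 (median 0.49, adjusted p = 3.4e-05; adjusted p = 0.926 with an estimated correlation, as for the lists that follow). C1qc, C1qb, C1qa at 1.74 and Spic, the factor gene of red pulp macrophages, at 1.14 passed adjusted over the list alone. Endothelial markers read higher in 9 of 11 (median 0.73, adjusted p = 6.3e-05), and Clec4g at 2.20 and the scavenger receptor gene Stab2 at 1.01 passed adjusted over the list alone. Natural killer and cytotoxic markers read higher in 7 of 9 (median 0.45, adjusted p = 0.0399), with the receptor gene Klre1 at 2.28 and the granule gene Nkg7 at 1.52 passing adjusted over the list alone and Prf1 passing in the other direction at -1.23. Neutrophil markers (13 of 14, median 0.64, adjusted p = 0.0101), oxidative phosphorylation genes (19 of 23, median 0.29, adjusted p = 0.0131) and adipocyte markers (4 of 6, median 0.45, adjusted p = 0.0346) were higher too. The adiponectin gene Adipoq, at least 2.35-fold higher, passed adjusted over the list alone. In 6 lists without a call, 9 members passed, 6 higher and 3 lower, Cxcl10 among the NF-kB targets being 1 of them. With the authors' normalized values the killer cell and neutrophil calls ended (medians 0.23 and 0.48, adjusted p = 0.134 and 0.0772), and without background correction the killer cell call ended (median 0.30, adjusted p = 0.0628).

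By limma, 0 features passed at 0.2 mg/ml in spleen, with a smallest adjusted p of 0.0828, and 805 had an unadjusted p under 0.05, 462 higher and 343 lower, against 210 with 75th percentile scaling and 247 with the arrays at 0.2 mg/ml averaged. The count was 1 without replicate 62_86, 5 with an intensity trend and robust hyperparameters, and 82, with all 10 genes named here, with all arrays fitted together. It was 673 without replicate 56 and 516 without replicate 32, with the spread again from replicates 62 and 62_86 alone. Serpina3f read 2.73 (SE 0.30), C1qc 2.44 (SE 0.27), C1qb 2.30 (SE 0.26) and Cxcl10 2.53 (SE 0.29), each with an adjusted p of 0.128, and C1qb and C1qc passed with the trend and robust hyperparameters (adjusted p = 0.0459 and 0.0339). Zbtb2 read -1.89 (SE 0.28), the proteasome subunit gene Psmb1 -1.59, Amy2a5 -1.49, the major urinary protein gene Mup2 -1.47 and Rufy2, a gene of vesicle traffic, -1.29. Supt16 read 0.04 (-0.05 with 75th percentile scaling), Cdkn1a 0.53 and Nfkbia 0.25, each with an adjusted p of 1.00.

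**Figure D2:**
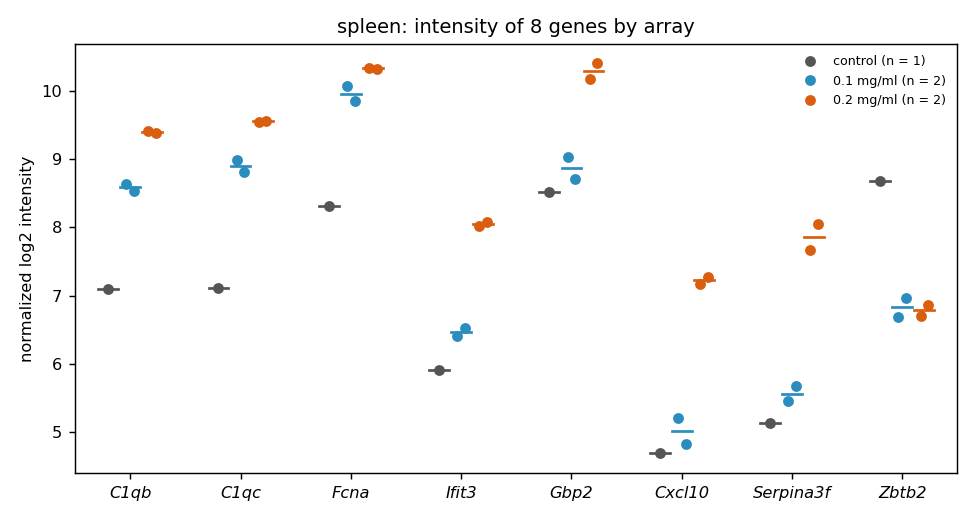
Log2 intensity (y axis) of 8 genes on the 5 spleen arrays, by group (x axis), where points are arrays and lines are group means. C1qb read 7.09 in the control, 8.64 and 8.54 at 0.1 mg/ml, and 9.41 and 9.38 at 0.2 mg/ml.

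Between the doses in spleen, interferon response genes read higher and cell cycle, erythroid and neutrophil genes lower at 0.2 than at 0.1 mg/ml, in list tests chosen after the data had been seen and without the control array in the means. Interferon response genes read higher in 28 of 32 (median 0.57, adjusted p = 2.3e-11; adjusted p = 0.533 with an estimated correlation). Ifit3 at 1.58, Gbp2 at 1.42, the interferon-induced GTPase gene Ifi47 at 1.26 and Oasl2 at 1.04 passed adjusted over the list alone, against 0 over all genes. Cell cycle genes read lower in 28 of 29 (median -1.13, adjusted p = 3.3e-13; adjusted p = 0.677 with an estimated correlation, as for the other lists here unless given). Erythroid markers read lower in 9 of 11 (median -1.38, adjusted p = 5.1e-04), with the anion exchanger gene Slc4a1 at -1.70 and Ermap at -2.00 passing adjusted over the list alone. Neutrophil markers read lower in 13 of 14 (median -0.86, adjusted p = 0.00156; adjusted p = 0.692 with an estimated correlation). Killer cell markers (8 of 9, median 0.49, adjusted p = 8.0e-04), macrophage markers (8 of 11, median 0.65, adjusted p = 0.00107), fibroblast markers (10 of 13, median 0.39, adjusted p = 0.00943), dendritic cell markers (7 of 8, median 0.53, adjusted p = 0.0102) and adipocyte markers (4 of 6, median 0.39, adjusted p = 0.0221) read higher. Klre1 at 1.78, Spic at 1.18, C1qb at 0.81, the macrophage receptor gene Adgre1 at 0.81 and Adipoq at 1.28 passed adjusted over the list alone. In lists without a call, Cxcl10, the T cell co-stimulator gene Cd28 at 1.24 and Dnajb1 at -1.03 passed. Without replicate 32, 2 of the 9 calls were kept, the neutrophil median turned to 0.10, and the medians were -0.10 (erythroid), 0.56 (macrophages), 0.24 (killer cells), 0.41 (fibroblasts), 0.03 (dendritic cells) and 0.28 (adipocytes). The fibroblast and adipocyte calls ended also without replicate 56 (0.52 and 0.50), and they and the dendritic cell call without replicate 62_86 (0.30, 0.30 and 0.46).

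By limma, 1 of 14179 features differed between the spleen doses, the probe ILMN_2835423, which the table used here does not name. It read 3.50 higher at 0.2 mg/ml (SE 0.23, adjusted p = 0.0259), with 4.29 on the control array, 4.21 and 4.53 at 0.1 mg/ml, and 7.82 and 7.93 at 0.2 mg/ml. The count of 1 fell to 0 with 75th percentile scaling, no background correction, the authors' normalized values, an offset of 50, no detection filter or the strict detection filter. It was 55 with all arrays fitted together, and 1724 without replicate 56 and 1147 without replicate 32, with the spread of the last 2 from replicates 62 and 62_86 alone. An unadjusted p under 0.05 was found for 1278, 699 higher and 579 lower, against 662 with 75th percentile scaling and 430 with the arrays at 0.2 mg/ml averaged. Serpina3f read 2.29 (SE 0.24) and Cxcl10 2.21 (SE 0.24), each with an adjusted p of 0.199, the guanylate-binding gene Gbp2b 1.91 and Gvin1, an interferon-inducible GTPase gene, 1.77. Ifrd2 read -1.93 (adjusted p = 0.274), the antibody heavy chain gene Ighg1 -1.60, Tatdn2 -1.18, the cell cycle factor gene E2f4 -1.27 and Yipf2 -1.07. Supt16 read 0.50, Cdkn1a -0.96 and Nfkbia 0.04 (-0.24 with 75th percentile scaling), with adjusted p from 0.541 to 0.988.

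**Figure D3:**
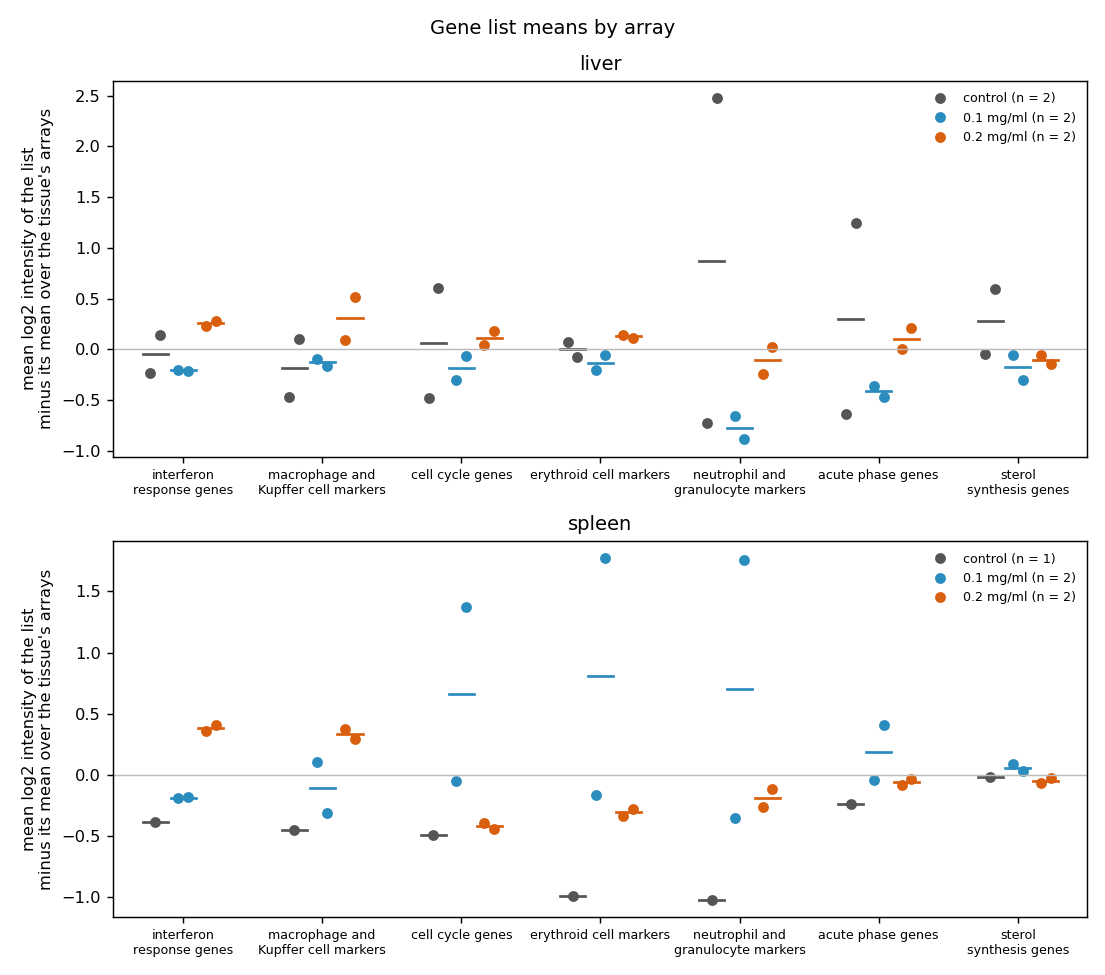
Mean log2 intensity of the genes of 7 lists relative to the tissue mean (y axis) on each liver and spleen array, by group (x axis), where dots are arrays and lines are group means. Interferon response genes stood at 0.36 and 0.41 on the spleen arrays at 0.2 mg/ml, -0.19 on each at 0.1 mg/ml and -0.39 on the control.

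Either dose against control in spleen brought the complement genes to the front. C1qc read 2.12 (SE 0.24) and C1qb 1.90 (SE 0.24), each with an adjusted p of 0.321, and Fcna read 1.83. The coagulation inhibitor gene Tfpi read 1.65 and Pilrb1, an activating receptor gene, 1.81. Zbtb2 read -1.87, Amy2a5 -1.67, Rufy2 -1.39, Prf1 -1.47 and the small nuclear RNA gene Rnu6 -1.68. By limma, 0 features passed, and 1026 had an unadjusted p under 0.05, 513 higher and 513 lower, against 308 with 75th percentile scaling and 470 with the arrays at 0.2 mg/ml averaged, both fewer than chance gives, 709. The count was 49 with all arrays fitted together, with 9 of the 10 genes, and 1497 without replicate 56 and 1096 without replicate 32, with the spread of these 2 from replicates 62 and 62_86 alone. Interferon response genes read higher in 27 of 32 (median 0.45, adjusted p = 3.9e-07; adjusted p = 0.812 with an estimated correlation), and 6 passed adjusted over the list alone, led by Ifit3 at 1.35 and Ifi27l2a at 1.36. Neutrophil (13 of 14, median 1.34, adjusted p = 3.0e-05), cell cycle (27 of 29, median 0.64, adjusted p = 9.0e-05), erythroid (11 of 11, median 1.36, adjusted p = 2.7e-04) and endothelial genes (9 of 11, median 0.60, adjusted p = 4.7e-04) read higher. So did oxidative phosphorylation (19 of 23, median 0.36, adjusted p = 8.1e-04), macrophage (8 of 11, median 0.45, adjusted p = 0.00348) and heat shock genes (15 of 21, median 0.26, adjusted p = 0.0416). For these 7 lists the adjusted p was 0.828 with an estimated correlation. The neutrophil, cell cycle and erythroid lists stood at 1.76, 1.38 and 1.77 on replicate 32 and at -0.35, -0.05 and -0.16 on replicate 56, and at 0.2 mg/ml alone cell cycle and erythroid genes had no call (adjusted p = 0.897 and 0.130). Clec4g at 1.80, C1qc, C1qb and C1qa at 1.42 passed adjusted over the list alone, as did 11 members of 7 lists without a call, 6 higher and 5 lower, against 0 over all genes. The heat shock call ended without replicate 56 (0.12) or 62 (0.22). Supt16 read -0.21, Cdkn1a 1.01 and Nfkbia 0.23, with adjusted p from 0.687 to 0.923.

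A direct test asked which genes responded to treatment differently in the organs. Fcna, C1qb and C1qc differed, since they read higher in treated spleen and nearly level in treated liver. For Fcna the change was 0.12 in liver and 2.16 in spleen, a difference of -2.04 (SE 0.21, adjusted p = 0.0256). The changes of C1qb were 0.18 and 2.08 (difference -1.90, SE 0.20, adjusted p = 0.0256), and those of C1qc 0.15 and 2.32 (difference -2.18, SE 0.25, adjusted p = 0.0334). All 4 arrays of treated spleen read above the single control for these 3 genes. The other 3 of the 6 features called, 1 higher and 5 lower, were probes without a name here. ILMN_2615739 differed by -2.35 and ILMN_2483493 by -1.65, with liver means of 4.16 to 4.34, near the 4.16 of undetected Cd22. A fall in liver could not be seen for these probes, and their differences are close to the spleen changes alone, 2.42 and 1.71. ILMN_1251193 differed by 2.71, with a change of -2.77 in spleen. An unadjusted p under 0.05 was found for 1476 of 16179 features, where chance gives 809, and for 805 with 75th percentile scaling. The count fell to 0 with 75th percentile scaling, with the spleen arrays at 0.2 mg/ml averaged, and without liver control replicate 25, liver replicates 43, 55 or 85, or spleen replicates 62 or 62_86. It was 1 without liver replicate 73, 11 without liver control replicate 1, 290 without spleen replicate 56 and 215 without spleen replicate 32.

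Of the p53 and NF-kB target lists, 1 was called in 1 comparison, the NF-kB targets between the liver doses. That test was chosen after the data had been seen, and the call was lost with an estimated correlation (adjusted p = 0.729) and without replicate 55 (0.0939) or 85 (0.0950). Targets of p53 had a smallest adjusted p of 0.150 over the 4 liver comparisons and 0.552 over those in spleen, and NF-kB targets one of 0.254 in spleen. Of the FACT subunits only Supt16 is named by a probe in the table used here, too few for a list test, and Ssrp1 and Trp53 are named by none. The other probe of Supt16 went the opposite way in 7 of the 8 comparisons within a tissue and that of Nfkbia in 6, so neither gene has a direction that holds across its probes. In the comparisons that name them, Ablim3, Mcm7, Mup2 and Yipf2 also had a probe that went the opposite way, as had Prf1 in 1 of 3. Smallest adjusted p in liver were 0.302 for immediate early genes, 0.520 for CAR and PXR targets, 0.561 for AhR targets, 0.194 for PPAR-alpha targets, 0.621 for bile acid genes and 0.495 for clock genes. In spleen these lists gave 0.254, 0.22, 0.735, 0.174, 0.735 and 0.214. Cytosolic ribosomal protein genes gave 0.358 in liver and 0.250 in spleen, glycolysis and hypoxia genes 0.151 and 0.216, and hepatocyte markers 0.170 and 0.576. B cell markers gave 0.152 and 0.0560, T cell markers 0.0565 and 0.137, plasma cell markers 0.303 and 0.440, platelet markers 0.152 and 0.639, and exocrine pancreas markers 0.131 and 0.218. Female-biased liver genes (0.503), skeletal muscle markers (0.710) and mammary genes (0.358) were tested in liver alone, and cholangiocyte markers (0.645) in spleen alone.

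The changes at the lower dose were set against those at the higher dose across genes. In liver their correlation across 12800 features was 0.393, against 0.50 (range 0.474 to 0.525) in 100 simulations of unchanged groups with the same shared controls. The signs matched for 61.3% of features, against 66.6% in the simulations. The covariance was 0.0280, against 0.0224, a difference of 0.00559. In spleen the correlation across 14179 features was 0.608, against 0.667 (range 0.649 to 0.679), with 73.8% matching signs against 73.2%. The covariance was 0.127, against 0.0787, a difference of 0.0482. Genes are not independent replicates, but the simulations drew each gene independently and with the same spread in every group. Their ranges may therefore be too narrow to judge a departure from them. The controls are too few to split, so part of any excess may come from the shared controls. The liver correlation was 0.692 without control replicate 25 and 0.664 without control replicate 1, where simulations of unchanged groups with 1 control gave 0.667 and 0.668. With 75th percentile scaling it was 0.519, against 0.501 in simulations.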

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

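All of the tests of explanations in this part were chosen after the results had been seen. A test of the difference between tissues singled out 6 features whose measured change from control was not the same in liver and spleen. Each spleen change rests on the single control array. The liver change minus the spleen change was -2.04 for Fcna, -1.90 for C1qb and -2.18 for C1qc. For the unnamed probes it was -2.35 (ILMN_2615739), -1.65 (ILMN_2483493) and 2.71 (ILMN_1251193). In liver ILMN_2615739 and ILMN_2483493 read near the floor, at means of 4.16 to 4.34, where a fall could not be seen. Chance gives 809 features at an unadjusted p under 0.05 in this test and 1476 were found, but 805 with 75th percentile scaling.

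C1qb, C1qc and Fcna, which code for subunits of the first complement component and for ficolin A, are made by tissue macrophages, and they read higher on all 4 treated spleen arrays than on the control array. More macrophages in general cannot be judged from the other 8 macrophage markers, with C1qa left out, though they rose less. Their median change was 0.11 (95% interval over genes -0.35 to 0.55), below the lowest change of the 3 genes less its SE, 1.58. The 3 genes were picked by their small p-values, so a lower median of the rest was likely beforehand. The whole macrophage list was called higher for either dose, a call lost with an estimated correlation. The normalization and background correction are argued against as the whole cause, since the difference nearest to 0 under any processing was -1.65, for C1qb with an offset of 50. With 75th percentile scaling, though, the calls ended because the SE rose from 0.20 to 0.38 for C1qb, 0.25 to 0.41 for C1qc and 0.21 to 0.40 for Fcna, with differences of -1.90, -2.15 and -1.94 (adjusted p = 0.836, 0.678 and 0.839), and with the spleen arrays at 0.2 mg/ml averaged the adjusted p was 0.160 for each. A drug-induced rise of these genes in spleen is a hypothesis that cannot be told apart from a low reading of the lone control, above which every treated array lay by at least 1.45. A change in macrophage number, in general or in a subset, stays open.

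Cell cycle, erythroid and neutrophil genes stood out on the spleen array of replicate 32 at 0.1 mg/ml. Mean values of these lists relative to the tissue mean were 1.38, 1.77 and 1.76 there, and -0.05, -0.16 and -0.35 on the other array of the dose. The mean signal was 94.7 on replicate 32 and 219 on replicate 56, with 40.0% and 42.5% of probes detected. Whether this difference in signal plays a part was not tested. B cell, T cell, killer cell and dendritic cell markers stood at -0.54, -0.41, -0.55 and -0.75 on replicate 32. Fewer lymphocytes as the whole cause would raise the markers of other cells too. Those of macrophages, endothelium, fibroblasts and platelets differed between the arrays by -0.10 (95% interval over genes -0.35 to -0.01), against 1.62 (1.46 to 1.88) for the 3 lists. This argues against fewer lymphocytes as the whole cause, for this pair of arrays only. The 3 lists were picked for standing high on replicate 32, and the intervals do not measure the spread between mice. Without background correction the 3 lists stayed called higher at 0.1 mg/ml than in control, with a lowest list median of 1.01. That median averages replicates 32 and 56, so it cannot tell how far replicate 32 stands out without the correction. An effect of 1 mouse cannot be told apart from a response to the dose, because the dose has 1 other array, and its share of replicate 32's distance from the control, at most 0.30, restates the pattern.

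Interferon response genes stood higher on the spleen arrays at 0.2 mg/ml than on any other spleen array. The control has no part in the gap between arrays at 0.2 and 0.1 mg/ml, at least 0.54, so a low control reading cannot account for that gap. The arrays of any group in either tissue lay at most 0.38 apart. The pattern was picked with this gap in view, so the gap restates it and is no separate support. Whether a low control reading adds to the rise above control stays open. More macrophages cannot be told apart from an interferon response by the list medians, which differed by 0.23 with a 95% interval of -1.03 to 0.74. Whether both arrays came from 1 animal, as their shared number 62 might mean, stays open as well. They correlated at 0.989, above the highest spleen pair of different groups (0.979) and below the highest liver pair of one group (0.992). The only other spleen pair of one group, replicates 56 and 32, correlated at 0.9485.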

How the results depend on the processing

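The list tests between doses and the left-out treated arrays of the dose correlation were chosen after seeing the data. Counts are genes with an adjusted p under 0.05, and the cause of a changed count was not tested unless stated. With 75th percentile scaling, the liver counts were 1 at 0.2 mg/ml and 1 between doses, and the counts between spleen doses and between tissues were 0 and 0. The same scaling gave a spleen dose correlation of 0.542, against 0.667 in unchanged groups simulated under it, and turned Supt16 in liver with either dose (-0.0577), Supt16 in spleen at 0.2 mg/ml (-0.0531) and Nfkbia between spleen doses (-0.24). With an intensity trend and robust hyperparameters together the counts were 3 in liver at 0.2 mg/ml, 3 between liver doses and 5 (4 higher, 1 lower) in spleen at 0.2 mg/ml. With all arrays fitted together they were 3 between liver doses, 48 (16 higher, 32 lower) in spleen at 0.1 mg/ml, 82 (68 and 14) at 0.2 mg/ml, 55 (43 and 12) between spleen doses and 49 (30 and 19) for either dose. Between liver doses, the authors' normalized values gave 2 and the strict filter 1. Between spleen doses the count of 1 became 0 with no background correction, the authors' values, an offset of 50, no detection filter and the strict filter. Between tissues the count of 6 became 12 with no background correction, 12 with the authors' values, 19 with an offset of 50, 13 with no detection filter and 0 with the spleen arrays at 0.2 mg/ml averaged, a fit with fewer samples. With an estimated correlation, the lists called were 0 in each of the liver and spleen comparisons, against 6 to 9 with the preset one. The estimate rests on 3 residual degrees of freedom in liver and 2 in spleen. In simulated data it called a list shifted by 0.5 in liver (adjusted p = 0.0450) and missed it in spleen (adjusted p = 0.850). Those genes were drawn independently, so the simulation cannot tell false calls with the preset correlation from power lost with the estimated one. The cause of the lost calls was not tested.

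Leaving out 1 array at a time gave 0 to 273 genes in liver at 0.1 mg/ml, 0 to 572 at 0.2 mg/ml, 0 to 187 between doses and 0 to 199 for either dose. In spleen it gave 0 to 1996 at 0.1 mg/ml, 0 to 673 at 0.2 mg/ml, 1 to 1724 between doses and 0 to 1497 for either dose, and 0 to 290 between tissues. The high spleen counts, without replicate 56 or 32, take their spread from replicates 62 and 62_86 alone. The high liver counts, without a control array, take theirs from the treated pairs alone, which were more alike than the controls. The lists called ran from 4 to 13 in liver at 0.1 mg/ml, with 4 without control replicate 25. The dose correlation in liver ran from 0.327 without replicate 55 to 0.692 without control replicate 25, where simulated unchanged groups of those sizes gave 0.407 and 0.667. In spleen it ran from 0.509 without replicate 56 to 0.604 without replicate 62, where they gave 0.579 and 0.577. Ranges that crossed 0 were, in liver at 0.1 mg/ml, -0.36 to 0.0328 for interferon response genes, -0.85 to 0.19 for acute phase genes, -0.81 to 0.20 for cell cycle genes and -3.94 to 0.0259 for neutrophil markers. Neutrophil markers ranged from -3.33 to 0.14 at 0.2 mg/ml and -3.63 to 0.0807 for either dose in liver, and from -1.82 to 0.10 between spleen doses. Gluconeogenesis genes ranged from -0.0405 to 0.55 for either dose in liver. Cdkn1a in liver ranged from -1.11 to 0.74 at 0.1 mg/ml, -0.34 to 1.5 at 0.2 mg/ml and -0.72 to 1.12 for either dose. Nfkbia ranged from -0.43 to 0.20 at 0.1 mg/ml, -0.44 to 0.19 between doses and -0.39 to 0.0413 for either dose in liver. In spleen its ranges were -0.33 to 0.75 at 0.1 mg/ml, -0.50 to 0.58 between doses and -0.0344 to 0.50 for either dose. Hspa1b between liver doses ranged from -0.26 to 0.78, and Supt16 in spleen at 0.2 mg/ml from -0.16 to 0.25.

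For the 220 values of named genes, 2043 processing alternatives left 1967 on the same side of the threshold and in the same direction, with 66 newly past it, 7 no longer past it and 3 turned. Only Fcna, C1qb and C1qc between tissues were past it in the main setting. Values no longer past it, here and with an array left out, can thus come from these genes alone, and most others stayed short of it. Of 1159 values with an array left out, 852 stayed the same, 269 were newly past the threshold, 22 no longer and 16 turned. For the 63 list calls, 189 processing alternatives kept 122 and ended 67, 63 of them by the estimated correlation. Of 327 values of these calls with an array left out, 260 stayed the same, 59 ended and 8 turned. No setting with another scaling moved the median of all genes by over 0.1. No paired analysis was possible because the groups share no replicate numbers. The signal over background limits the dim genes, since 35.8% to 43.2% of probes were detected.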

Other observations

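Interferon response genes separated the doses in both organs, in a comparison of arrays chosen after the pattern had been seen. On the liver arrays the list mean relative to the tissue mean was 0.23 and 0.28 at 0.2 mg/ml and -0.20 and -0.22 at 0.1 mg/ml, while the controls lay at -0.24 and 0.14. In liver the lowest gap between an array at 0.2 and one at 0.1 mg/ml was 0.43, against a gap of 0.38 between the control livers and of at most 0.0485 within a dose. In liver the values at 0.1 mg/ml lie between those of the 2 controls, and both values at 0.2 mg/ml lie above them. That the higher dose may raise these genes in both organs is a hypothesis resting on this liver gap and the spleen gap of 0.54. An exact permutation test of the doses within each tissue restates these gaps, with a two-sided p of 0.0556, the smallest possible over 36 arrangements, and takes replicates 62 and 62_86 as separate animals. Macrophage markers read higher at 0.2 mg/ml too (liver median 0.41, adjusted p = 0.0112; spleen median 0.65, adjusted p = 0.00107), calls lost with an estimated correlation (adjusted p = 0.729 and 0.677) and without liver replicate 55 or 85 or spleen replicate 32. Whether macrophages account for the pattern stays open, and the spleen arrays at 0.2 mg/ml might be from 1 animal. Measuring these genes and macrophage numbers in further animals at each dose would test it.

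Liver control replicate 25 carried a pattern of its own that the labels do not explain. Its list means relative to the liver mean were 2.48 for neutrophil markers, 1.25 for acute phase genes, 0.60 for cell cycle genes, 0.60 for sterol synthesis genes and 0.52 for fatty acid synthesis genes. The other control liver read -0.72 for neutrophil markers and -0.47 for cell cycle genes.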
